A study of Mus musculus with 42 samples.

How the data were processed

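Sorted CD4+ T cells of mice were measured on Agilent whole-genome oligonucleotide arrays. The 42 arrays held 21 biological samples, each hybridised to 2 technical arrays. Per the labels, regulatory T cells (Treg) were sorted from spleen and lymph nodes by a Foxp3-GFP reporter or by high CD25 and GITR, and conventional T cells (Tconv) by the absence of both proteins. Which sort was used for which group is not given in the sources used here. Groups were taken from the sample titles and hold 3 or 4 samples each. The files pair the Tconv and Treg of an animal through an animal tag in the sample descriptions, not through the replicate number, which only names a sample here.

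Per the file headers, the intensity values of each spot and of its local background were extracted with Agilent Feature Extraction 10.1.1.1 under a 2-colour protocol, and the probes were annotated on the mouse build mm8. Per the labels, RNA was labelled with Cy5 only, so the red channel holds the sample. The green channel lay close to its own background, yet 17.8% of probes on the median array were well above background there, and the median Spearman correlation of green with red over spots was 0.642. The processed red signal in the same files, per the file headers, had been background-subtracted and dye-normalised against that nearly empty green channel, so the mean signal was used instead. The deposited series table holds log2 values. Its scale was read from slopes of 0.853 to 1 between its differences and those of scanner values on 40 of 42 arrays. Centring per probe was inferred as 52.5% of row medians lay within 0.001 of 0. Its column medians ran from -0.0166 to 0.0487, and how the authors normalised it stays unknown. It was used as an alternative.

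Red mean intensities were corrected with the normexp method at an offset of 50 on all spots, control spots and outlier spots (0.284% of the others) were left out, log2 values were quantile-normalised between the 42 arrays, and spots of a probe and then the 2 technical arrays of a sample were averaged. Of 41174 probes, 31749 were well above background in red on both arrays of at least 3 of the 21 samples. Each gene was represented by its brightest passing probe, which left 21671 rows (17186 with a gene symbol and 4485 without) after 47 rows with a missing value were removed. Symbols came from accessions for 23374 probes, from the current symbol for 6733 and from a synonym for 2919, while 1256 kept the name in the files and 6892 had none. No spot was saturated. The median red signal per array ran from 148.9 to 779.5 (median 309.8) against a local background of 74 to 252, and 55.7% to 74.9% of probes were well above background. The number of samples limits the precision of every comparison.

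Differences were tested with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), with all 6 groups in 1 linear model, empirical Bayes moderation and Benjamini-Hochberg adjustment at 0.05. Every adjusted p of a gene below comes from that test. It is two-sided, and SE is the moderated standard error of a log2 difference. The 10 contrasts were the Treg of 1B3.RAGKO against those of 1B3 and NOD, 1B3 Treg against NOD Treg, Treg against Tconv in each strain, 1B3.RAGKO Tconv against the other Tconv, and the interactions that compare the Treg effect of 1B3.RAGKO with that of 1B3 and of NOD. The 21 gene lists were tested with limma's camera at a preset correlation of 0.01, two-sided, with adjustment over the lists of a contrast, and again with the correlation estimated from the data. The 210 list tests gave 89 past the threshold with the preset and 36 with the estimated correlation. Lists covered the regulatory T cell signature, 5 genes recalled from the published study, effector Treg and activation, naive and quiescent T cells, TCR-induced immediate genes, T helper cytokines and regulators, cell cycle, interferon response, the TGF-beta pathway, homing and chemokine receptors, the IL-2 and STAT5 pathway, costimulation and TCR complex, and markers of B cells, monocytes, macrophages and neutrophils, dendritic cells, NK cells, CD8 T cells, thymocytes, erythroid cells, platelets and megakaryocytes, and animal sex. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

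Named genes followed a rule: among genes with an ordinary symbol past the threshold whose 2 groups did not overlap, the 10 largest rises and 10 largest falls of each comparison of 1B3.RAGKO Treg with another Treg, 5 and 5 of each Treg and Tconv comparison, each interaction and 1B3 Treg against NOD Treg, and 4 and 4 of each Tconv comparison. For each list described, the 2 to 4 passing members with the largest difference were added, or else the member with the smallest p. Foxp3, Il2ra, Tnfrsf18, the 5 recalled genes, Rag1, Rag2, Xist, Ddx3y and Eif2s3y were always examined. Some genes that the rule named are not reported here, while counts and list tests include them. A call was described as not overlapping where every sample of a group lay on 1 side of every sample of the other. Where a probe was not well above background on any array of a group, the fold is a lower bound against the dimmest probes measured on the same arrays and is written as at least that fold. Where a probe was well above background on some arrays of a group, the fold is the plain one and the number of such arrays is given.

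Groups, tests, filter, lists, named genes and the alternatives were fixed before the data were examined, except for 3 alternatives chosen after seeing them: leaving out 1 library, labelled NOD_Treg replicate 1, from the list tests and from comparisons that do not use it, leaving out 4 libraries that stood apart, and a covariate of monocyte, macrophage and neutrophil markers. The alternatives fixed beforehand were the processed signal, 75th percentile scaling, the series values, the median signal, other filters and probe rules, a model of only the groups compared, all 42 arrays with the sample as a block, the slide and the animal as blocks, array weights, variance trends, and each library left out in turn. Deviations from the group means correlated between the Tconv and Treg of the same animal with r = 0.294, 0.241 and 0.229 in 1B3, 0.159, 0.185 and 0.181 in 1B3.RAGKO, and 0.16, 0.027 and 0.048 in NOD, across genes, which are not independent replicates. Between different animals it ran from -0.36 to 0.226, -0.28 to 0.148 and -0.29 to 0.218, so in NOD the same-animal values were not the highest. The animal tag is a shared animal, so it was used as the replicate block. On simulated data with 200 of 21671 rows changed, the comparison of 1B3.RAGKO Treg with 1B3 Treg recovered 32.8%, 86.6% and 95.5% of rows changed by 1, 2 and 3 on the log2 scale, with 7 false calls.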

Results

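The series compared Foxp3+ Treg, which restrain immune responses, and Foxp3-negative CD4+ Tconv from 3 kinds of mice. 1B3 mice carry a transgenic T cell receptor for myelin basic protein. The 1B3.RAGKO mice carry the same receptor without a recombination-activating gene, so their T cells cannot rearrange other receptors, and their Treg are described by the submitters as induced, with more than 90% Foxp3+ cells. NOD mice are the wild-type nonobese diabetic strain and, like 1B3, gave total Treg. The groups were 1B3_Tconv (n = 4), 1B3_Treg (n = 3), 1B3.RAGKO_Tconv (n = 3), 1B3.RAGKO_Treg (n = 4), NOD_Tconv (n = 4) and NOD_Treg (n = 3), each sample averaged over 2 technical arrays. Levels are normalised log2 red intensities, given as mean ± SD over the samples of a group.

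Foxp3, the transcription factor that defines Treg (probe on chromosome X, 6751991 to 6752050, build mm8), was 14.35, 14.75 and 14.88 in the 1B3_Treg samples, 16.37, 14.9, 15.34 and 15.41 in 1B3.RAGKO_Treg, and 14.45 and 15.09 in NOD_Treg replicates 2 and 3. It was 9.51, 7.57, 8.88 and 9.45 in 1B3_Tconv, 8.6, 10.59 and 9.42 in 1B3.RAGKO_Tconv, and 9.6, 8.52, 10.12 and 8.91 in NOD_Tconv. In the library labelled NOD_Treg replicate 1 it was 10.63, next to the Tconv values. Both scanner files of that library correlated with their own columns of the series table with r = 0.06 and 0.078 across probes, against at least 0.931 for each of the other 40 arrays. Comparisons with NOD_Treg include this library. Their counts of rows, and the values and list calls that it moved by over 1.5 times or across the threshold among those described, are also given without it. It lay on slide 1, while every other NOD sample lay on slides 9 to 14 and every 1B3 and 1B3.RAGKO sample on slides 1 to 8. Strain and set of slides therefore cannot be told apart in any comparison with NOD, and a block for single slides does not separate them. No slide held both Treg and Tconv of a strain. Rag2, a recombination-activating gene (chromosome 2, 101433127 to 101433186), was dim, being well above background on 1 to 6 arrays of each group: 6.96 ± 0.15 in 1B3_Treg, 7.31 ± 0.27 in 1B3_Tconv, 8.01 ± 0.9 in 1B3.RAGKO_Treg, 7.28 ± 0.66 in 1B3.RAGKO_Tconv, 7.3 ± 0.41 in NOD_Treg and 8.08 ± 0.92 in NOD_Tconv, and from 6.76 to 9.43 over the 21 samples. No Rag1 probe passed the filter, the labels do not say which gene was deleted, and a probe outside the deleted part checks nothing. The Y-linked Eif2s3y was between 15.35 and 16.64 in every sample and Xist, which is transcribed in females, between 7.32 and 8.49.

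**Figure D1:**
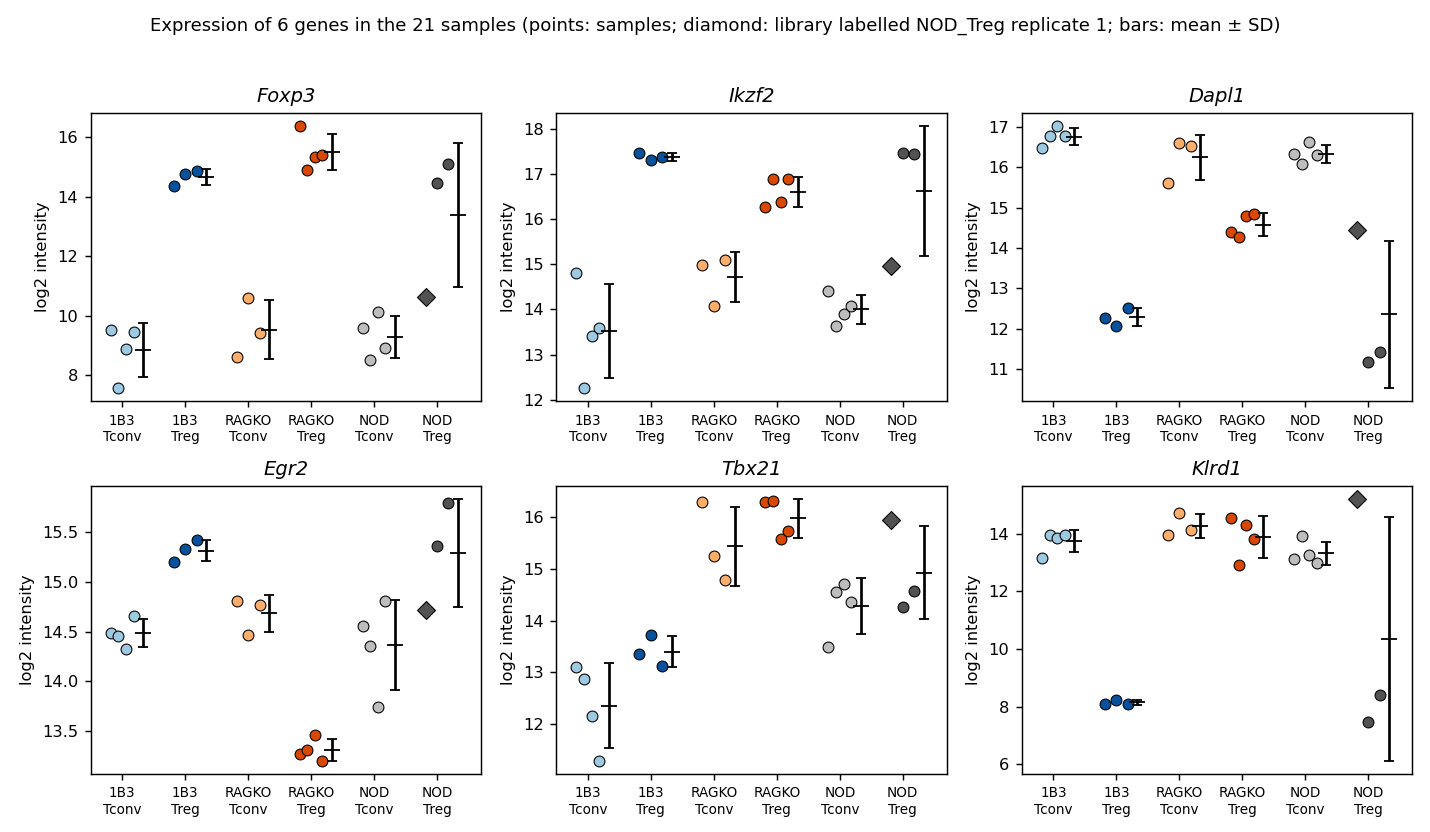
Each panel plots the normalised log2 red intensity of a gene (y axis) in the 6 groups (x axis), with points for samples, bars for the mean ± SD and a diamond for the library labelled NOD_Treg replicate 1. Foxp3 sat at 14.35 or above in every Treg sample except the diamond at 10.63, Egr2 lay lower in 1B3.RAGKO_Treg (13.31 ± 0.11) than in 1B3_Treg (15.32 ± 0.11), and Klrd1 was 8.15 ± 0.08 in 1B3_Treg against 13.9 ± 0.72 in 1B3.RAGKO_Treg.

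How Treg differed from Tconv was read in each strain. In 1B3 mice, 28 of the 30 measured genes of the regulatory T cell signature rose in 1B3_Treg over 1B3_Tconv and none fell (30 adjusted over the list alone; median log2 difference 3.56, camera adjusted p = 1.4e-64, and adjusted p = 8.11e-05 with an estimated correlation). Klrg1, an inhibitory lectin-like receptor of effector lymphocytes, was 77.9-fold higher (log2 difference 6.28 ± 0.66 SE, adjusted p = 1.2e-05), Socs2, a feedback inhibitor of cytokine signalling, 66.1-fold (6.05 ± 0.47), and the protease granzyme B, encoded by Gzmb, 54.2-fold (5.76 ± 0.85). Foxp3 (56-fold) and Il2ra (87.1-fold), which encodes CD25, also led the rises, but both served the sort and are no finding. Tnfrsf18, the gene of GITR, did not pass (log2 difference 0.43, adjusted p = 0.189). The largest falls were Ggt5 (102-fold; chromosome 10, 75058627 to 75058686), Pdlim4 (56.3-fold), the lectin-like receptor gene Klrd1 (48.4-fold), Lrrc75b (42.5-fold) and Dapl1 (22.2-fold). None of these genes overlapped between the groups, and Klrg1 was well above background on 7 of the 8 1B3_Tconv arrays.

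Of 25 effector and activation genes, 21 rose in 1B3_Treg and none fell (24 and none adjusted over the list alone; median 2.55, adjusted p = 7.77e-45, estimated 0.000168), among them the integrin gene Itgae (48.9-fold) and the IL-33 receptor gene Il1rl1 (29.2-fold). Cell cycle genes rose for 12 of 28 members (25 adjusted over the list alone; median 1.83, adjusted p = 2.38e-25, estimated 0.026), led by Tk1 (8-fold), Ccna2, Ccnb2 and Ube2c. Homing receptors rose for 8 of 22 (10 higher and 1 lower adjusted over the list alone; median 1.22, adjusted p = 5.75e-08, estimated 0.00161), with Ccr2 11.2-fold and Ccr6 9.13-fold higher. In the IL-2 and STAT5 list 7 of 19 rose and Il7r fell (8 and 2 over the list alone; median 0.46, adjusted p = 1.27e-07, estimated 0.00373), with the receptor chain Il2rb 6.46-fold and the inhibitor Cish 4.92-fold higher. Naive and quiescent genes fell for 7 of 20 (9 over the list alone; median -0.46, adjusted p = 2.57e-09, estimated 0.00161), including Tdrp by 2.63 and Il7r by 1.7 on the log2 scale. Among T helper genes Il12rb1 (4.92-fold), Rora (3.09-fold) and Il18r1 (2.36-fold) rose (4 higher and 1 lower over the list alone; median 0.51, adjusted p = 9.48e-05, estimated 0.0154). Markers of other cells were lower alongside, in lists that lost the call with the estimated correlation. B cell markers fell for 2 of 19, Cr2 among them (5.45-fold, measured on 2 of the 6 1B3_Treg arrays; 2 higher and 7 lower over the list alone; median -0.64, adjusted p = 0.00326, estimated 0.237). Dendritic cell markers had no passing member (none over the list alone; median -1.1, adjusted p = 0.0252, estimated 0.396). In camera run on the moderated t statistics both calls ended with the animal as the replicate block, from adjusted p = 0.000743 to 0.073 for B cells and from 0.0409 to 0.0929 for dendritic cells.

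Of the 5 genes recalled from the study's publication, and so chosen on these samples and not independent evidence, Nrp1 (22.1-fold; chromosome 8, 131388840 to 131388899), Ikzf2 (14.5-fold) and Swap70 (4.4-fold) rose in 1B3_Treg while Dapl1 and Igfbp4 (3.78-fold) fell. In all, 898 rows passed in 1B3_Treg against 1B3_Tconv, 669 higher and 229 lower. That count was 537 without 1B3_Tconv replicate 2, 583 without 1B3_Tconv replicate 4, and 387 and 407 without 1B3_Treg replicates 2 and 3. It was 1874 where only the groups compared were fitted. With any 1 library left out, 30 of the 41 named genes past the threshold kept the call. Those that lost it included Ccna2, Ccnb2, Dntt, Il18r1, Nr4a1, Oas2, Rora, Tgif1 and Ube2c. Calls lost numbered 4, 7, 5 and 5 without 1B3_Tconv replicates 1 to 4, and 6, 10 and 11 without 1B3_Treg replicates 1 to 3. Gzmb was 6.44 and 5.14 on the log2 scale without 1B3_Tconv replicates 1 and 3. With the animal as the replicate block, Nr4a1 did not pass (log2 difference 0.77).

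The same question was asked in NOD mice. In NOD_Treg, 25 of 30 signature genes rose over NOD_Tconv and none fell (29 adjusted over the list alone; median 2.7, adjusted p = 1.21e-43, and 0.00075 with an estimated correlation). Klrg1 was 54.7-fold higher (log2 difference 5.78 ± 0.66 SE, adjusted p = 5.84e-05), the opioid precursor gene Penk 48.8-fold, the decoy IL-1 receptor gene Il1r2 45.4-fold and Gzmb 43.4-fold, beside the sorted Il2ra (44.8-fold). Ggt5 (43.9-fold), Pdlim4 (33.3-fold), Lrrc75b (25.4-fold), P4ha2 (17.7-fold) and Dapl1 (15.7-fold) were the largest falls. Klrg1 and Il2ra were well above background on 7 of the 8 NOD_Tconv arrays and, of the 6 NOD_Treg arrays, P4ha2 on 5, Fcer2a on 4 and Cr2 on 2. Effector and activation genes rose for 18 of 25 (22 over the list alone; median 1.87, adjusted p = 7.24e-31, estimated 0.00125), with Itgae 33.7-fold and Tnfrsf9 14.7-fold higher. Naive genes fell for 5 of 20 (11 over the list alone; median -0.76, adjusted p = 3.32e-08, estimated 0.00333), including Tdrp and Satb1. Cell cycle genes rose for 13 of 28 (24 over the list alone; median 1.72, adjusted p = 5.66e-22, estimated 0.0352), led by Tk1 (8.62-fold), and for 3 without the library labelled NOD_Treg replicate 1. TCR-induced immediate genes rose for 4 of 23 (6 over the list alone; median 0.43, adjusted p = 2.63e-06, estimated 0.0251): Dusp1 6.34-fold, Tnfaip3 3.29-fold, Egr2 1.9-fold and Nr4a1 1.89-fold. B cell markers fell for 5 of 19 (7 over the list alone; median -0.79, adjusted p = 2.27e-06, estimated 0.0474), among them Fcer2a (8.84-fold), Cr2 (6.66-fold) and Ms4a1. Dendritic cell markers were lower with no passing member (none over the list alone; median -1.31, adjusted p = 0.0123, estimated 0.422). Interferon response genes fell for 2 of 26, Oas2 (10.2-fold) and Ddx58 (2.14-fold), and that list's call ended with the estimated correlation (2 over the list alone; median -0.4, adjusted p = 0.00424, estimated 0.525).

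In NOD_Treg against NOD_Tconv, Foxp3 was 17.2-fold higher (log2 difference 4.1 ± 0.79 SE, adjusted p = 0.00436), Ikzf2 6.14-fold and Igfbp4 5.31-fold lower, while Nrp1 did not pass (log2 difference 2.49 ± 0.74 SE, adjusted p = 0.0661). Swap70 (2.8-fold) and Egr2 passed although their groups overlapped. Without the library labelled NOD_Treg replicate 1, the log2 differences were 5.48 for Foxp3, 3.84 for Nrp1, which then passed, 3.45 for Ikzf2, 2.25 for Swap70 and -2.82 for Igfbp4. The falls were then larger, at -7.21 for Ggt5, -5.9 for Pdlim4, -5.7 for Lrrc75b, -5.02 for Dapl1 and -2.78 for Tdrp. Il2ra (6.3) and Tnfrsf9 (4.73) were also further from 0, and Il1r2 (4.66), Gzmb (4.84), Tnfaip3 (1.12), Ccna2 (2.14) and Ifng (1.54) nearer to it. As lists without it, the signature had a median of 3.35, effector and activation genes 1.72, cell cycle 1.28, T helper genes 0.38 and interferon response genes -0.21, with that call ended. NK markers went from 0.01 to -0.66 and then passed with the preset correlation. Without NOD_Treg replicate 2, Ggt5 was -4.75 and Dapl1 -3.39, and without replicate 3, Ggt5 was -4.4, Foxp3 3.25, Dusp1 3.31, Ifng 3.03 and Fcer2a -3.74. Gzmb was 6.3 without NOD_Tconv replicate 1 and Il1r2 4.91 without NOD_Tconv replicate 3. The comparison gave 922 rows, 627 higher and 295 lower, 614 and 585 without NOD_Treg replicates 2 and 3, and 334 where only the groups compared were fitted. Without the library labelled NOD_Treg replicate 1 it gave 807, of which 580 were also among the 922. Of 48 named genes past the threshold, 34 kept the call with any 1 library left out. Calls lost numbered 6, 9 and 11 without NOD_Treg replicates 1, 2 and 3 (Ccna2, Ddx58, Gpr15, Ifng, Rrm2 and Tnfaip3 without the first), and 1, 5, 8 and 5 without NOD_Tconv replicates 1 to 4. In a model with the animal as the replicate block Nrp1 passed (log2 difference 2.64), and Swap70 (1.44), Egr2 (0.72), Ddx58 (-1.04), Tgfbr1 (1.14) and Fcer2a (-3.2) did not. Under 75th percentile scaling the median of all rows moved from -0.083 to -0.616, so small list medians have no settled sign (T helper genes 0.68, adjusted p = 7.32e-05, and -0.02 under that scaling). It put TCR-induced genes at 0.26, B cell markers at -2, dendritic cell markers at -2.02, and ended the interferon call. In the series table the medians were 1 for cell cycle, 0.37 for T helper and -0.03 for interferon response genes.

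In 1B3.RAGKO mice fewer members of the signature passed: 10 of 30 rose in 1B3.RAGKO_Treg over 1B3.RAGKO_Tconv and none fell (15 adjusted over the list alone; median 1.19, adjusted p = 5.49e-19, and 0.0146 with an estimated correlation). Foxp3 was 62.7-fold and Il2ra 29.9-fold higher, as sorted. Il1rl1 rose 36.2-fold (log2 difference 5.18 ± 0.42 SE, adjusted p = 1.75e-06), Gzmb 35.2-fold, the leukotriene receptor gene Ltb4r1 32.1-fold and Socs2 20.5-fold. The lipid receptor gene S1pr5 (21.7-fold), Ggt5 (12.4-fold), Lypd6b (7.45-fold), Adh1 (7.33-fold) and Serpinh1 (6.2-fold) fell most. S1pr5 was well above background on 6 of the 8 1B3.RAGKO_Treg arrays, and Ltb4r1, Havcr2, Nusap1, Cdk1 and Bub1 on 4 of the 6 1B3.RAGKO_Tconv arrays. Cell cycle genes rose for 23 of 28 (26 over the list alone; median 1.97, adjusted p = 3.74e-30, estimated 0.0242), with Nusap1 12.8-fold, Cdk1 10.6-fold, Bub1 9.88-fold and Rrm2 9.01-fold higher. Effector and activation genes rose for 11 of 25 (14 higher and 2 lower over the list alone; median 1.07, adjusted p = 4.07e-12, estimated 0.0276), including Havcr2 (21.6-fold) and Itgae (18.6-fold). The costimulation and TCR complex list fell for 3 of 19, Cd28 by 1.25, Btla by 1.23 and Zap70 by 0.61 on the log2 scale (3 over the list alone; median -0.34, adjusted p = 0.00025, estimated 0.0146). The naive list fell for Tdrp and Tcf7 (10 over the list alone; median -0.51, adjusted p = 6.3e-06, estimated 0.0146). Dendritic cell markers were lower with no passing member (none over the list alone; median -0.88, adjusted p = 0.0048, estimated 0.374). The monocyte, macrophage and neutrophil list did not pass (median -0.89, adjusted p = 0.132). In a test on ranked statistics it passed with the animal as the replicate block (median -1.86, adjusted p = 0.00537, and 0.163 without the block). Egr2, an early response gene of TCR signalling, fell 2.59-fold. Of the recalled genes none passed: Nrp1 was 1.04, Ikzf2 1.88, Swap70 0.83, Dapl1 -1.66 and Igfbp4 -0.97 on the log2 scale.

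The 1B3.RAGKO comparison gave 804 rows, 552 higher and 252 lower (68.7% higher, and 86% with the processed signal, which moved the median of all rows from -0.044 to 0.119). The count was 513 without 1B3.RAGKO_Tconv replicate 2 and 409 without 1B3.RAGKO_Treg replicate 4, 1321 with the slide as a random block, and 52 where only the groups compared were fitted. Of 33 named genes past the threshold, Adh1, Egr2, Foxp3, Gzmb, Il18r1, Il1rl1, Il2ra, Itgae, Ltb4r1, Lypd6b, Nusap1, Pim1, S1pr5, Socs2, Tdrp and Tgfbr2 kept the call with any 1 library left out. Calls lost numbered 8, 14 and 3 without 1B3.RAGKO_Tconv replicates 1 to 3, and 2, 5, 7 and 11 without 1B3.RAGKO_Treg replicates 1 to 4. Serpinh1 (log2 difference -2.88) did not pass with the animal as the replicate block. Without 1B3.RAGKO_Tconv replicates 1 and 2 the log2 differences were 6.19 and 3.95 for Ltb4r1, 5.66 and 3.27 for Havcr2, 4.81 and 2.38 for Nusap1, 4.15 and 2.3 for Cdk1, 4.1 and 2.31 for Bub1, and 4.09 and 2.05 for Rrm2. Serpinh1 was -1.92 without the first and -3.56 without replicate 3, and S1pr5 -3.79 without the second and -5.06 without 1B3.RAGKO_Treg replicate 1. Under 75th percentile scaling the naive list had a median of -0.28, costimulation and TCR complex -0.13 and dendritic cells -0.54.

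Whether the Treg effect itself differed was tested with interactions. The signature separated Treg from Tconv less in 1B3.RAGKO than in 1B3 (median difference of effects -1.71, adjusted p = 1.25e-24, and 0.00625 with an estimated correlation), with 3 of 30 members passing by themselves (15 adjusted over the list alone): Penk, Il2rb and the costimulatory receptor gene Tnfrsf4. Levels show the form of the difference. Penk was 10.17 ± 1.39 in 1B3_Tconv and 15.47 ± 0.75 in 1B3_Treg but 15 ± 1.48 in 1B3.RAGKO_Tconv and 15.65 ± 0.43 in 1B3.RAGKO_Treg. Tnfrsf4 was 14.39 ± 0.22 and 17.76 ± 0.33 in the 1B3 groups and 16.03 ± 0.24 and 17.47 ± 0.2 in the 1B3.RAGKO groups. Against 1B3 the homing list behaved likewise (2 of 22 lower, Ccr9 and Ccr8, and 5 over the list alone; median -1.15, adjusted p = 2.35e-08, estimated 0.00441). So did effector and activation genes (Ccr8, Irf4 and Pdcd1 lower, 9 over the list alone; median -1.07, adjusted p = 1.56e-12, estimated 0.0389). Egr2 was 14.48 ± 0.14 in 1B3_Tconv and 15.32 ± 0.11 in 1B3_Treg, and 14.68 ± 0.18 and 13.31 ± 0.11 in the corresponding 1B3.RAGKO groups. The difference of effects was -2.21 ± 0.34 SE (adjusted p = 0.00696). Against 1B3, the largest positive differences were Nacc2 (4.78), Lrrc75b, Pdlim4, Slpi and Cacnb4 and the largest negative ones Ptger3 (-5.83), Penk, Pla2g4f, the T cell receptor gamma gene Tcrg and Capn3. With the processed signal the effector and activation median was -0.52. The B cell list was higher, with Cr2 as its passing member (3 over the list alone; median 0.32, and 0.72 under 75th percentile scaling; adjusted p = 0.00326, estimated 0.262). In camera run on the moderated t statistics that call ended with the animal as the replicate block (adjusted p = 0.0011, and 0.174 with the block). Some of the gene values rest on signals near background. Ptger3 was well above it on 1 of the 8 1B3_Tconv and 6 of the 8 1B3.RAGKO_Treg arrays, so the size and rank of its difference are not settled, Cacnb4 on 2 of the 6 1B3.RAGKO_Tconv arrays, Pla2g4f on 7 and Ccr8 on 6 of the 8 1B3_Tconv arrays.

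The difference of effects passed for 68 rows against 1B3 (18 higher and 50 lower) and for 116 rows against NOD (37 higher and 79 lower). Against NOD, Nacc2 (4.88), Fam20a, Slpi, the B cell gene Ms4a1 and Tgfb3 were the largest positive and Ptger3 (-5.03), Penk, C2cd4b, Capn3 and Pla2g4f the largest negative differences, and Egr2 differed by -2.3 ± 0.34 SE (adjusted p = 0.00381). Of the 8 NOD_Tconv arrays, Ptger3 was well above background on 2, C2cd4b on 3, Ccr8 on 4 and Pla2g4f on 7, and of the 6 1B3.RAGKO_Tconv arrays Fam20a was on 5 and Ms4a1 on 4. Cr2 was not well above background on any 1B3.RAGKO array, so its differences of effects have no settled size. The signature list against NOD had a median of -0.8 (2 lower, 9 over the list alone; adjusted p = 8.23e-09, and 0.112 with an estimated correlation). That median was -0.45 under 75th percentile scaling, -1.5 in the series table and -1.44 without the library labelled NOD_Treg replicate 1. The B cell list was higher against NOD too, with 3 of 19 members passing (4 over the list alone; median 0.92, and 1.8 under 75th percentile scaling; adjusted p = 2.57e-05, estimated 0.122), and 1 without that library. Effector and activation genes were lower for 4 of 25 (2 higher and 8 lower over the list alone; median -0.81, -0.03 under 75th percentile scaling and -0.37 in the series table; adjusted p = 0.000107, estimated 0.287), and homing receptors for Ccr8 (6 over the list alone; median -0.22, and 0.1 under that scaling; adjusted p = 0.00374, estimated 0.109). TCR-induced genes were lower for Egr2 against NOD (11 over the list alone; median -0.76, and -0.33 with the processed signal; adjusted p = 2.19e-07, estimated 0.062) and against 1B3 (1 over the list alone; median -0.46, and -0.12 under that scaling; adjusted p = 0.00095, estimated 0.134). With the processed signal all 6 rows passing against 1B3 were lower, where 26.5% of the 68 were higher, and the median of all rows moved to 0.204. Against NOD 75th percentile scaling moved it to 0.723. Leaving out 1 library gave 33, 33 and 30 rows against 1B3 without 1B3_Tconv replicates 2, 3 and 4, and 27, 25 and 23 without 1B3_Treg replicates 1 to 3. It gave 41 without 1B3.RAGKO_Tconv replicate 3, 44, 43 and 34 without 1B3.RAGKO_Treg replicates 2 to 4, and 167 without the library labelled NOD_Treg replicate 1. Against NOD it gave 71 and 67 without 1B3.RAGKO_Treg replicates 3 and 4, 64 and 77 without NOD_Tconv replicates 2 and 4. It gave 60 without NOD_Treg replicate 2 and 207 without the library labelled NOD_Treg replicate 1, which included 94 of the 116. Calls lost against NOD without that library included Ms4a1 and Cd44. Dapl1 (3.36) and Igfbp4 (1.85) then passed, C2cd4b was -4.23, and the NK (1.09) and cell cycle (0.72) lists passed with the preset correlation, from 0.51 and 0.36 with it. Capn3, Egr2, Nacc2, Ptger3 and Slpi kept the call in both interactions with any 1 library left out. So did Il2rb, Pdcd1, Tcrg and Tnfrsf4 against 1B3, and C2cd4b, Ccr8, Cr2, Fam20a and Tgfb3 against NOD. Fitting only the groups compared gave 147 rows against 1B3 and 28 against NOD. Between 3 and 10 of the 19 named calls in each were lost without any given library. Against 1B3, Penk was -5.32 without 1B3_Tconv replicate 1, Nacc2 4.16 without 1B3_Treg replicate 1 and Ptger3 -5.22 without 1B3.RAGKO_Treg replicate 1. Without 1B3.RAGKO_Tconv replicate 1 Penk was -5.5, Pla2g4f -5.22 and Tcrg -4.97, without replicate 2 Lrrc75b 3.56, and without replicate 3 Tcrg -3.45. Against NOD, Ms4a1 was 2.88, Penk -5.81 and Pla2g4f -4.69 without 1B3.RAGKO_Tconv replicate 1, Ptger3 -4.42 and C2cd4b -5.66 without 1B3.RAGKO_Treg replicate 1, and C2cd4b -5.58 without NOD_Treg replicate 3. The animal as the replicate block ended the call of Lrrc75b (difference of effects 4.38), Pdlim4 (3.66), Tcrg (-4.08), Irf4 (-1.92), Cr2 (2.17) and Prf1 (1.9) against 1B3. Against NOD it ended that of Ms4a1 (2.99), Tnfrsf4 (-1.41), Pdcd1 (-2.17), Irf4 (-1.82) and Prf1 (1.94).

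The induced Treg were compared first with 1B3_Treg, which share the transgenic receptor. In 1B3.RAGKO_Treg, 6 of 12 natural killer (NK) cell markers rose and 5 of 23 TCR-induced genes fell, the second list losing its call with an estimated correlation. Klrd1 rose 53.8-fold (13.9 ± 0.72, n = 4, against 8.15 ± 0.08, n = 3; chromosome 6, 129564066 to 129564125; log2 difference 5.75 ± 1.12 SE, adjusted p = 0.0182), Klrc2 26.4-fold, Klrk1, which encodes NKG2D, 19.8-fold, Klrb1b 19-fold and the granzyme gene Gzmk 30-fold. The interferon-induced membrane protein genes Ifitm1 (37.4-fold; chromosome 7, 140820876 to 140820935) and Ifitm7 (14.2-fold) rose as well, with the kinase gene Dapk2 (27.7-fold), the MHC class II gene H2-Eb1 (16.7-fold) and the adhesion gene Dscam (15.4-fold). Largest among the falls were Dnahc7c (24.4-fold), Sh3gl3 (21.3-fold), the iron reductase gene Cybrd1 (21-fold; chromosome 2, 70943488 to 70943547), C1ql3 (19-fold), Zan (18.1-fold), Lypd1 (11.3-fold), Galnt14 (10.5-fold), Noxa1 (9.87-fold), the netrin gene Ntn4 (9.12-fold) and Cavin1 (8.37-fold). The samples of the groups did not overlap for any of these 20 genes, and other probes of Dnahc7c differed in sign. Several were dim in 1 group. Of the 8 1B3.RAGKO_Treg arrays, Zan was well above background on 1, Lypd1 and Noxa1 on 3, Sh3gl3 on 4, Ntn4 on 5, Dnahc7c on 6 and Galnt14 on 7. Of the 6 1B3_Treg arrays, Dapk2, Klrc2, Klrk1, Klrb1c and Ncr1 were on 5 and Il12rb2 on 3.

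Of 12 measured NK markers, Klrd1, Klrk1, Klrb1c (7.95-fold), Ncr1 (7.22-fold), Nkg7 (3.78-fold) and Prf1 rose and none fell (8 adjusted over the list alone; median 1.81, camera adjusted p = 3.51e-14, and 0.0335 with an estimated correlation). Prf1 and Nkg7, genes of cytotoxic granules, are also transcribed in T cells, and Klrd1 was 13.74 ± 0.38 in 1B3_Tconv. Markers of monocytes, macrophages and neutrophils were also higher, with no member past the threshold (2 over the list alone; median 1.67, adjusted p = 0.000735, and 0.418 with an estimated correlation; Tyrobp 3.62 ± 0.97 SE, adjusted p = 0.0933). S100a9 was 16.19, 8.79, 13.87 and 8.81 in 1B3.RAGKO_Treg and 7.03, 9.1 and 7.46 in 1B3_Treg. Of 23 TCR-induced genes, Egr2 (4.02-fold; chromosome 10, 66937367 to 66937426; adjusted p = 0.00131), Egr3 (3.82-fold), Nr4a1 (2.98-fold), Egr1 (2.75-fold) and Cd5, whose protein restrains TCR signalling, fell (6 over the list alone). That list's median was 0.04, its mean -0.3 and its test downward (adjusted p = 0.00162, and 0.212 with an estimated correlation), and the median was 0.35 under 75th percentile scaling. The costimulation and TCR complex list was lower, with Cd5 as its passing member (1 over the list alone; median -0.23, adjusted p = 0.00205, estimated 0.0335), although its median was 0.03 under 75th percentile scaling.

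Among effector and activation genes in 1B3.RAGKO_Treg, Pdcd1, which encodes the inhibitory receptor PD-1, fell 5.22-fold (14.01 ± 0.33 against 16.4 ± 0.37) while the chemokine receptor gene Cxcr3 rose 4.95-fold (9 higher and 3 lower over the list alone; median 0.48, adjusted p = 0.000735, and 0.299 with an estimated correlation). T helper genes past the threshold were the type 1 genes Ifng (6.32-fold higher), Tbx21 (5.98-fold; chromosome 11, 96914193 to 96914252) and Il12rb2 (3.55-fold), with 7 higher and 1 lower over the list alone, and the list as a whole did not pass (median 0.09, adjusted p = 0.106). Il7r rose 3.66-fold, and the homing genes Itga4 (5.2-fold) and Ccr9 (3.98-fold) fell. Cell cycle genes were higher as a list with no single call and no estimated-correlation call (none over the list alone; median 0.94, adjusted p = 8.76e-10, estimated 0.253). The regulatory T cell signature did not pass as a list (median -0.17, and 0.16 under 75th percentile scaling; adjusted p = 0.12; 3 higher and 7 lower over the list alone), nor did Foxp3 (log2 difference 0.85 ± 0.79 SE, adjusted p = 0.803), Il2ra or Tnfrsf18. Of the recalled genes only Dapl1 passed (4.89-fold higher; chromosome 2, 59305606 to 59305665; 1 higher and 2 lower over the list alone, which is not independent evidence). Nrp1 was lower by -2.36 ± 0.74 SE (adjusted p = 0.178), Swap70 by -1.31 ± 0.41 SE and Ikzf2 by -0.78 ± 0.54 SE. Without the library labelled NOD_Treg replicate 1, which is in neither group but adds to the estimate of the spread, Nrp1 and Swap70 passed with the same differences. The signature (7 members lower) and T helper lists (5 higher) then also passed with the preset correlation, their medians being the same. The effector and activation median was 0.81 under 75th percentile scaling.

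In 1B3.RAGKO_Treg against 1B3_Treg, CD8 T cell markers (2 measured, 2 higher over the list alone) had a median of 1.48 and passed (adjusted p = 0.00669, estimated 0.155). Markers of dendritic cells (median 0.73, adjusted p = 0.163), erythroid cells (1.51, 0.106), platelets and megakaryocytes (0.28, 0.114), thymocytes (1.05, 0.106) and animal sex (-0.3, 0.106) did not pass, nor did B cell markers (median 0.01, mean 0.25, test downward, adjusted p = 0.928). The interferon response (median 0.12, adjusted p = 0.3), TGF-beta pathway (-0.15, 0.163), homing (0.1, 0.928), IL-2 and STAT5 (0.24, 0.12) and naive lists (median -0.25, mean 0, adjusted p = 0.384) did not pass either. Over the lists alone between 0 and 4 members were higher and between 0 and 3 lower in each.

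In this comparison 202 rows passed, 98 higher and 104 lower. The higher share was 48.5%, against 62.2% of 37 rows under 75th percentile scaling and 71.1% of 38 with the processed signal, and these moved the median of all rows from 0.011 to 0.156 and 0.106. Slides 5 and 6 each held a sample of both groups. The median difference of the 202 rows, signed by the call, was 2.07 and 2.34 within those slides against 2.2 over all samples, in genes chosen on these same samples, and 640 rows passed with the slide as a random block. Within the slides the NK list shifted by 1.44 and 1.84 (1.89 with the block), cell cycle by 1.69 and 0.8 (0.89), and effector and activation by 1.28 and 0.87 (0.67). CD8 markers shifted by 1.21 and 1.67 (1.42), costimulation and TCR complex by -0.25 and -0.34 (-0.27), TCR-induced genes by -0.17 and -0.26 (-0.01). The monocyte, macrophage and neutrophil list shifted by 0.39 and -0.17 (1.32). The count was 55, 42 and 46 without 1B3_Treg replicates 1 to 3, 134 and 74 without 1B3.RAGKO_Treg replicates 3 and 4, and 480, with all 202 among them, without the library labelled NOD_Treg replicate 1. It was 377 where only the groups compared were fitted. Of 37 named genes past the threshold, Cd5, Cxcr3, Cybrd1, Dscam, Egr2, Ifitm1, Ifitm7, Nr4a1 and Pdcd1 kept the call with any 1 library left out. Calls lost numbered 25, 26 and 27 without 1B3_Treg replicates 1 to 3, and 10, 10, 9 and 19 without 1B3.RAGKO_Treg replicates 1 to 4. Dapk2 was 4.19 on the log2 scale without 1B3.RAGKO_Treg replicate 1. Gzmk (log2 difference 4.77), H2-Eb1 (4.01) and Dnahc7c (-4.67) did not pass with the animal as the replicate block.

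Against the Treg of NOD mice, which shared no slide with them, 3 of 23 TCR-induced genes fell in the induced Treg. Egr3 fell 4.26-fold, Egr2 3.95-fold (13.31 ± 0.11, n = 4, against 15.29 ± 0.55, n = 3; log2 difference -1.98 ± 0.24 SE, adjusted p = 0.00159) and Nr4a1 2.39-fold (8 lower and 1 higher over the list alone; median -0.43, and -0.2 under 75th percentile scaling; adjusted p = 6.74e-08, and 0.0302 with an estimated correlation). Pdcd1 fell 4.72-fold, and the largest falls besides it were the guanylate cyclase gene Gucy1b1 (9.25-fold), Tbc1d4 (7.81-fold), the signalling inhibitor gene Spry1 (5.84-fold), the vasopressin receptor gene Avpr1a (at least 5.49-fold), Mctp1, Gna14, Rgs16, Gprasp2 and Dhrs3. The rises were led by Tcrg (8.65-fold; chromosome 13, 19312471 to 19312530), Cacnb4 (6.14-fold), the fucosyltransferase gene Fut7 (6.05-fold), Tctex1d1, Stc2, Pigz, B3gnt8, Tafa3, Muc20 and Apobr, with folds down to 4.88. No group overlapped for these genes. Tctex1d1 was well above background on 2 of the 6 NOD_Treg arrays and, of the 8 1B3.RAGKO_Treg arrays, Mctp1 on 2 and Gucy1b1 and Gna14 on 6. Prf1 was the only NK marker past the threshold (3.08-fold; 5 over the list alone; list median 1.22, adjusted p = 3.06e-06, and 0.22 with an estimated correlation). The 2 CD8 T cell markers were higher over the list alone (median 1.51, adjusted p = 0.00907, estimated 0.153). The costimulation and TCR complex list was lower (none passed, 1 over the list alone; median -0.23, and 0.01 under 75th percentile scaling; adjusted p = 0.00268, estimated 0.0302). The signature as a list did not pass (5 higher and 4 lower over the list alone; median 0.07, and -0.25 in the series table; adjusted p = 0.957), and neither did any recalled gene (Dapl1 2.22 ± 0.52 SE, adjusted p = 0.0836). T helper genes had a median of 0.17 and a mean of -0.03 with a downward test that did not pass (adjusted p = 0.721).

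This comparison gave 64 rows, 29 higher and 35 lower, and depends on the model and on which NOD_Treg libraries are used. Where limma was fitted to only the groups compared, 0 rows passed, with 2480 at an unadjusted p under 0.05. Without the library labelled NOD_Treg replicate 1, 435 rows passed, 60 of the 64 among them, and the log2 differences were 3.27 for Dapl1, -3.08 for Nrp1, -1.58 for Swap70 and 1.42 for Igfbp4, all past the threshold. They were then 3.36 for Fut7, 2.96 for Apobr, -3.85 for Gucy1b1, -3.88 for Tbc1d4, -3.45 for Spry1, -3.59 for Avpr1a, -3.19 for Mctp1 and -2.94 for Gprasp2. Mctp1 was -1.93 without NOD_Treg replicate 2 and Avpr1a -1.76 without replicate 3. Klrd1 was 15.22 in that library, against 7.45 and 8.4 in NOD_Treg replicates 2 and 3, and without it 6 of 12 NK markers rose (list median 1.6). The signature had a median of -0.33 without it and passed with the preset correlation, 7 members falling, and costimulation and TCR complex had one of -0.15. The monocyte, macrophage and neutrophil list had a median of 0.9 with that library (adjusted p = 0.171) and 1.43, past the threshold, without it. The count was 42, 33 and 6 without 1B3.RAGKO_Treg replicates 2, 3 and 4 and 2 and 8 without NOD_Treg replicates 2 and 3. A share of 66.7% of 6 rows was higher under 75th percentile scaling, which moved the median of all rows from 0.052 to 0.319, against 45.3% of the 64. Of 24 named genes past the threshold only Egr2 kept the call with any 1 library left out. Calls lost numbered 9, 11, 11 and 20 without 1B3.RAGKO_Treg replicates 1 to 4, and 0, 23 and 21 without NOD_Treg replicates 1 to 3. Fut7 (log2 difference 2.56), Tafa3 (2.27), Apobr (2.26) and Avpr1a (-2.56) did not pass with the animal as the replicate block.

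Both comparisons share the 1B3.RAGKO_Treg samples. They called 45 rows in the same direction, 19 higher and 26 lower, and 0 in opposite directions, where independent lists of these sizes would share 0.13 and 0.17. In 100 simulations where no group differed the overlap was 0 each time. Almost no row is called where nothing changed, so this does not show what the shared samples add to the 45. With the shared samples divided between the comparisons, 2 for each, the 6 divisions gave 3 to 5 rows. Across rows the log2 differences correlated with r = 0.794 against 0.43 simulated, and from 0.325 to 0.534 in those divisions. They had a covariance of 0.223 against 0.062 simulated. Where only the groups compared were fitted the overlap was 0, since none passed against NOD_Treg. Leaving out 1 library gave 15, 12 and 19 rows without 1B3_Treg replicates 1 to 3, 26 and 5 without 1B3.RAGKO_Treg replicates 3 and 4, 2 and 5 without NOD_Treg replicates 2 and 3, and 331 without the library labelled NOD_Treg replicate 1, where independent lists would share 2.3 higher and 2.5 lower.

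The Treg of 1B3 and NOD mice were set against each other as the 2 kinds of total Treg, again with no slide in common. No row passed in limma (0 rows, with 446 at an unadjusted p under 0.05), so Foxp3 (log2 difference 1.27 ± 0.84 SE), Il2ra, Nrp1, Ikzf2, Swap70 and Dapl1 all had an adjusted p of 1. Without the library labelled NOD_Treg replicate 1, 5 rows passed, and without NOD_Treg replicate 3, 1 row. As lists, NK markers (none passed; 1 lower over the list alone; median -0.65, adjusted p = 7.62e-06, and 0.309 with an estimated correlation), monocyte, macrophage and neutrophil markers (median -0.96, adjusted p = 0.0127, estimated 0.827) and T helper genes (1 lower over the list alone; median -0.28, adjusted p = 0.00046, estimated 0.105) were lower in 1B3_Treg. The T helper median was -0.07 in the series table and -0.18 without the library labelled NOD_Treg replicate 1. The NK median was 0.06 in the series table, and 0.02 without the library labelled NOD_Treg replicate 1, and the monocyte, macrophage and neutrophil median was -0.05 without it and -0.26 in the series table, both calls ending without it. With the processed signal these medians were -0.33 and -0.57. The cell cycle (0.28), naive (0.18) and CD8 T cell (0.59) lists, which did not pass with that library, passed without it with the preset correlation. The signature was higher (none over the list alone; median 0.36, adjusted p = 0.028, estimated 0.827), with a median of -0.15 without that library, -0.16 in the series table and 0.09 with the processed signal. Under 75th percentile scaling the median of all rows moved from 0.026 to 0.126.

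Tconv were then compared between strains. Effector and activation genes rose for 11 of 25 members in 1B3.RAGKO_Tconv over 1B3_Tconv and none fell (18 adjusted over the list alone; median 1.24, adjusted p = 1.56e-23, and 0.00437 with an estimated correlation), with Nkg7 20.6-fold and Cxcr3 12.7-fold higher. The signature rose for 10 of 30 (17 over the list alone; median 1.23, adjusted p = 1.6e-20, estimated 0.00959) in these Foxp3-low cells, among them Penk (28.6-fold; chromosome 4, 4060735 to 4060794), Ebi3 (14.4-fold) and Itgae (log2 difference 3.34). Foxp3 did not pass (log2 difference 0.68 ± 0.79 SE, adjusted p = 0.797). The largest rises were the T cell receptor gamma genes Tcrg (46-fold; log2 difference 5.53 ± 0.5 SE, adjusted p = 1.74e-05) and Tcrg-C (35.2-fold), S1pr5 (42.8-fold) and Klrg1 (32.3-fold), and the largest falls the IgM receptor gene Fcmr (13.8-fold), the prostacyclin receptor gene Ptgir (8.17-fold), Arhgap29 (7.93-fold) and Padi3 (7.23-fold). Of the 8 1B3_Tconv arrays, S1pr5 was well above background on 3 and Tcrg-C, Klrg1 and Klrk1 on 7. Of the 6 1B3.RAGKO_Tconv arrays, Fcmr was on 2 and Ptgir, Arhgap29, Padi3, Il4, Ms4a1 and Fcer2a on 4. Ptgir was 0.12 on the log2 scale where the filter required all 21 samples, which takes another probe. Homing receptors rose for 6 of 22 (11 higher and 2 lower over the list alone; median 0.91, adjusted p = 1e-08, estimated 0.00353), with Cxcr6 12.6-fold and Ccr2 8.74-fold higher. The IL-2 and STAT5 list rose for 3 of 19 (6 over the list alone; median 0.35, adjusted p = 0.000156, estimated 0.039), with Socs2 5.71-fold, Il2rb 4.11-fold and Socs1 2.06-fold higher. Tbx21 (8.49-fold) and Ifng (6.19-fold) rose and Il4 fell 3.12-fold, in a T helper list whose call ended with the estimated correlation (8 higher and 2 lower over the list alone; median 0.37, adjusted p = 0.00145, estimated 0.0559).

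Marker lists of other cells also passed between these Tconv, and none kept the call with an estimated correlation. B cell genes fell for 4 of 19 members (4 over the list alone; median -0.21, adjusted p = 0.00176, and 0.207 with an estimated correlation), among them Ms4a1 6.2-fold, Cr2 at least 5.82-fold and Fcer2a 5.75-fold. NK markers rose for 3 of 12 (6 over the list alone; median 1.13, adjusted p = 9.29e-07, estimated 0.127): Klrk1 16.1-fold, Klre1 at least 3.66-fold and Nkg7. Monocyte, macrophage and neutrophil markers were higher with no member past the threshold (none over the list alone; median 1.8, adjusted p = 0.000875, estimated 0.506). S100a9 was 16.99, 14.98 and 8.13 in 1B3.RAGKO_Tconv and 6.84, 14.48, 7.53 and 7.1 in 1B3_Tconv. The 2 CD8 T cell markers (1 higher over the list alone; median 1.19, adjusted p = 0.0188, estimated 0.137) and dendritic cell markers (none over the list alone; median 0.79, adjusted p = 0.0312, estimated 0.544) were higher as lists, with no member past the threshold. In all, 317 rows passed, 239 higher and 78 lower. Slides 2 and 3 each held a sample of both groups. The median signed difference of the 317 rows, chosen on these samples, was 1.91 and 1.86 within them against 2.07 over all samples. With the slide as a random block 636 rows passed. Within those slides effector and activation genes shifted by 2.22 and 1.15 (1.32 with the block) and the signature by 1.56 and 1.22 (1.22). The shifts were 1.02 and 0.21 (0.85) for homing, 0.12 and 0.28 (0.31) for IL-2 and STAT5, 0.78 and 0.62 (1.34) for NK markers, and 2.09 and -0.02 (1.74) for the monocyte, macrophage and neutrophil list. They were -0.34 and -0.66 (-0.29) for B cells, 1.6 and 1.33 (1.32) for CD8 T cells, and 1.69 and -0.01 (0.82) for dendritic cells. The count was 200 and 204 without 1B3_Tconv replicates 2 and 4, 209 and 702 without 1B3.RAGKO_Tconv replicates 2 and 3, and 144 where only the groups compared were fitted. Of 30 named genes past the threshold, 17 kept the call with any 1 library left out (Ccr2, Cr2, Cxcr3, Cxcr6, Ebi3, Fcmr, Il12rb1, Il2rb, Itgae, Klrg1, Nkg7, Penk, Pmepa1, S1pr5, Tbx21, Tcrg and Tcrg-C). Tcrg was 6.28 and 4.76, and Tcrg-C 5.89 and 4.4, on the log2 scale without 1B3.RAGKO_Tconv replicates 1 and 3. Without replicate 1 Arhgap29 was -3.67, Penk 5.69 and Ms4a1 -1.95, and without replicate 2 S1pr5 4.78, Ptgir -2.39, Arhgap29 -1.75 and Padi3 -2.2. Penk was 5.5 without 1B3_Tconv replicate 1. Under 75th percentile scaling the dendritic cell median was 0.49, without a call, and with the processed signal that of B cells was -0.69. Calls lost numbered 2, 5, 3 and 6 without 1B3_Tconv replicates 1 to 4, and 5, 8 and 3 without 1B3.RAGKO_Tconv replicates 1 to 3.

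**Figure D2:**
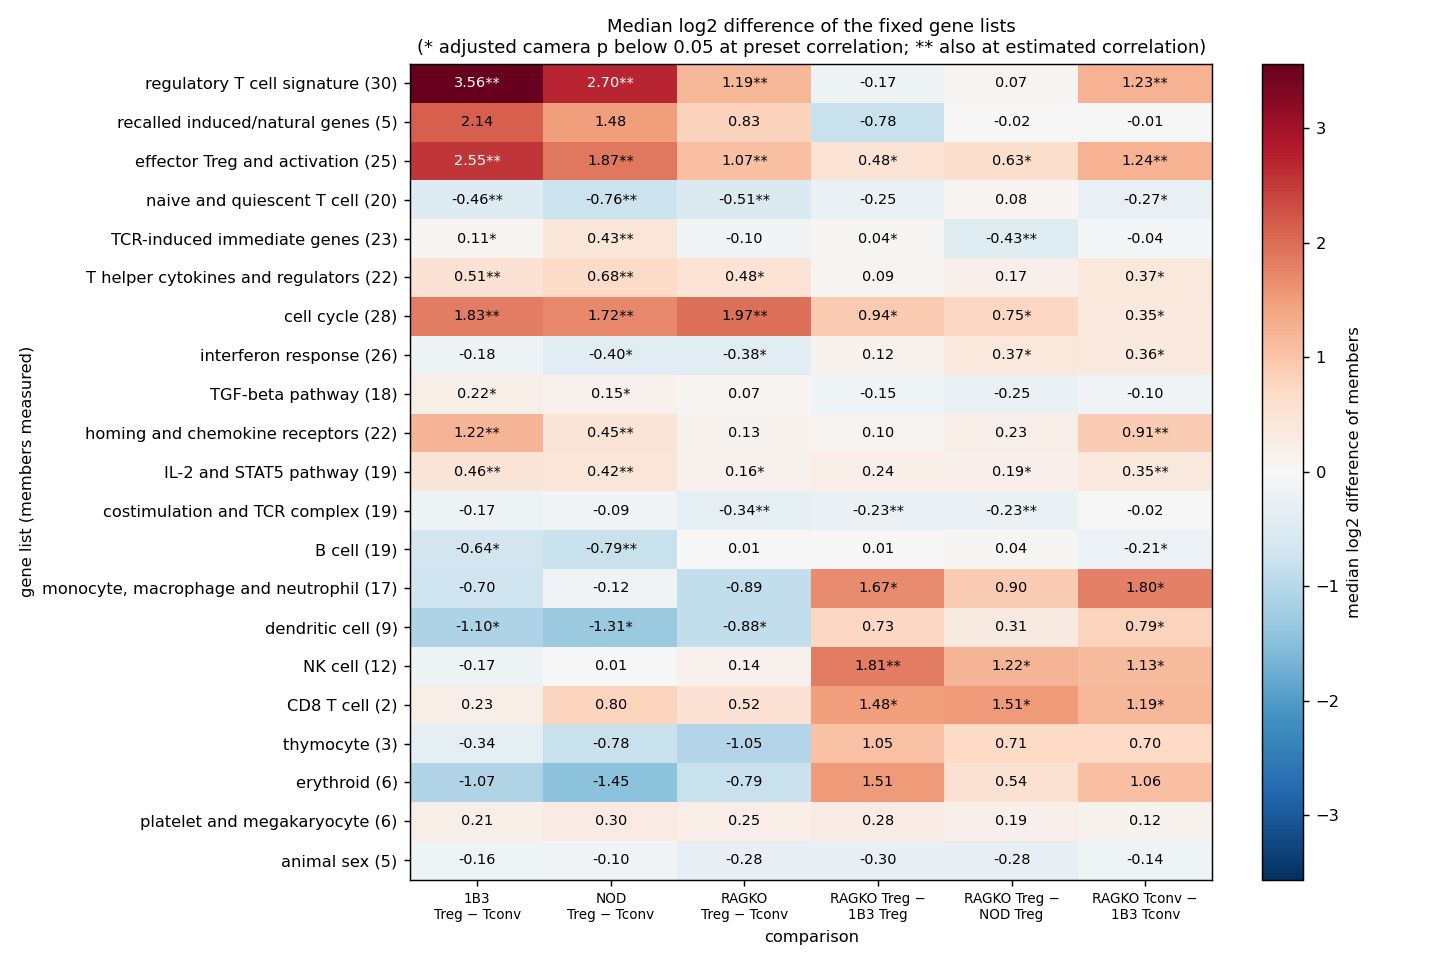
Colours give the median log2 difference of the members of each of 21 gene lists (rows) in 6 comparisons (columns), with 1 star where the camera adjusted p is below 0.05 with the preset correlation and another where it also is with the estimated one. The regulatory T cell signature had medians of 3.56, 2.7 and 1.19 for Treg over Tconv in 1B3, NOD and 1B3.RAGKO; between 1B3.RAGKO_Treg and 1B3_Treg it was -0.17, and 0.16 under 75th percentile scaling.

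The 1B3.RAGKO_Tconv were also set against NOD_Tconv, with which they shared no slide. Wnt10a, which encodes a signalling protein, rose 35.3-fold (15.98 ± 0.19, n = 3, against 10.84 ± 0.3, n = 4; chromosome 1, 74737266 to 74737325; log2 difference 5.14 ± 0.6 SE, adjusted p = 0.000338), Klrg1 31.5-fold, S1pr5 23.7-fold and Penk 19.3-fold. The falls were led by a T cell receptor beta joining probe, Tcrb-J (37.7-fold, with another probe of opposite sign), Fcmr (24.6-fold), Tmem273 (16.3-fold) and Fcer2a (12-fold). Of the 6 1B3.RAGKO_Tconv arrays, Tcrb-J was well above background on 1, Fcmr on 2, and Tmem273, Fcer2a, Il21, Il4 and Ms4a1 on 4. Of the 8 NOD_Tconv arrays, Klrg1 and S1pr5 were on 7, Ccr8 on 4 and Klre1 on 2. Effector and activation genes rose for 10 of 25 and 1 fell (16 higher and 1 lower over the list alone; median 1.17, adjusted p = 5.98e-12, and 0.0463 with an estimated correlation), with Lgals3 7.16-fold and Nkg7 6.86-fold higher. The signature rose for 7 of 30 (15 over the list alone; median 0.86, adjusted p = 3.34e-12, estimated 0.0463), led by Ebi3 (13.8-fold) beside Penk and with Itgae 7.19-fold higher. Homing receptors rose for 3 of 22 (9 higher and 1 lower over the list alone; median 0.63, adjusted p = 1.01e-05, estimated 0.0294), Cxcr3 5.58-fold and Ccr8 5.21-fold among them. Il12rb1 passed (2.58-fold) with overlapping groups. The interleukin genes Il21 (10.9-fold) and Il4 (7.64-fold) fell. B cell genes fell for 4 of 19 (7 over the list alone; median -0.39, adjusted p = 4.99e-06, estimated 0.0724), among them Ms4a1 (8.69-fold) and Cr2 (at least 6.67-fold). Lists of other cells were higher alongside, without a call under the estimated correlation. NK markers rose for Klre1 (3.4-fold) and Nkg7 (5 over the list alone; median 1.13, adjusted p = 0.00606, estimated 0.509), and 1 of the 2 CD8 T cell markers rose (2 over the list alone; median 1.78, adjusted p = 0.00258, estimated 0.055). Monocyte, macrophage and neutrophil markers had no passing member (none over the list alone; median 1.11, adjusted p = 0.042, estimated 0.675).

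This comparison also gave 317 rows, 212 higher and 105 lower, and 75th percentile scaling moved the median of all rows from 0.003 to -0.434 and that of B cell markers to -1.25. The homing median was 0.27 with the processed signal. Without 1B3.RAGKO_Tconv replicate 1 Penk was 5.12 and Ms4a1 -2.43 on the log2 scale, and without replicate 2 S1pr5 was 3.92 and Il21 -2.56. The count was 185 and 1187 without 1B3.RAGKO_Tconv replicates 2 and 3, and 70 where only the groups compared were fitted. Of 26 named genes past the threshold, 18 kept the call with any 1 library left out. Calls lost numbered 2, 7 and 3 without 1B3.RAGKO_Tconv replicates 1 to 3, and 3, 3, 2 and 3 without NOD_Tconv replicates 1 to 4.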

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

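All tests weighed in this part were chosen after the results they bear on had been seen.

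The scanner files of the library labelled NOD_Treg replicate 1 and its columns of the series table held different values. Its Foxp3 was 10.63, against at least 14.35 in every other Treg sample. A difference between animals, or other cells in the sample, explains this poorly, as the 2 sources describe the same arrays and correlated at 0.0601 and 0.0779 across probes. A swap with 1B3.RAGKO_Treg replicate 1 is argued against by the arrays of that sample, which correlated with their own columns at 0.998 or above. A wrong file or a wrong label may therefore be the explanation. The table columns correlated on average with NOD_Treg at r = 0.603 and with 1B3_Treg at 0.485. The scanner files did so with 1B3.RAGKO_Treg at 0.329, 1B3.RAGKO_Tconv at 0.185 and NOD_Treg at 0.0998. In the scanner files Tcrb-J was 6.86, against 11.14 to 13.15 in the other NOD samples and 6.7 to 7.64 in the 1B3.RAGKO samples. Klrc2 was 13.05, against 6.98 to 8.91 and 10.64 to 13.43, and Fcmr 8.39, against 10.7 to 12.54 and 6.73 to 9.71. Here the files lay within the 1B3.RAGKO values and outside the other NOD values. The library shared slide 1 with a 1B3 sample, as 1B3.RAGKO samples did on slides 2 to 7, but its source stays open.

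NK marker genes were higher in 1B3.RAGKO_Treg than in 1B3_Treg (6 of 12 members past the threshold, median 1.81). With the mean of the monocyte, macrophage and neutrophil markers as covariate, the median was 1.63, the lower quartile 0.59, and 3 members passed. Other cells in the sort stay open as part of the cause. NK cells might also be a source. Sorting on CD4 and Foxp3 or CD25 should remove them, yet S100a9 was 16.19 in 1B3.RAGKO_Treg replicate 1. Gzma, an abundant NK transcript, was higher by 3.4 and Klra1, Klra3, Klra7 and Klra8 by 0.37, 0.54, 1.13 and 0.38, without passing. Prf1 and Nkg7 are also T cell transcripts, and Klrd1 was as high in 1B3_Tconv as in 1B3.RAGKO_Treg. The list rose in 1B3.RAGKO_Tconv over 1B3_Tconv as well (median 1.13). Transcription by 1B3.RAGKO T cells, not only induced Treg, is a candidate that was not tested.

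The 202 genes that differed between 1B3.RAGKO_Treg and 1B3_Treg were also set against technical explanations. The groups lay on different array positions, but genes called without 2 of the 1B3.RAGKO_Treg samples differed the same way between those samples and NOD_Treg, which lay on the same positions of other slides, with a lowest median of 1.08 over 6 pairs of held-out samples. Within a slide that held both groups, genes called without its samples differed by a median of 1.89 (17 genes; the other such slide had 6, too few to count). With the monocyte, macrophage and neutrophil covariate the 202 genes kept a median of 2.04 with a lower quartile of 1.52, although the count fell to 94, of which 86 were among the 202. A difference in the cells remains a hypothesis, since strain background, the way the Treg arose and the other cells in each sort differ together between these groups.

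Other divisions of the same samples into groups of the same sizes showed how far chance can be excluded. For 1B3.RAGKO_Treg against 1B3_Treg, 1 of 35 divisions gave 202 genes or more, the real one, and the highest other gave 14, so chance is excluded at that share. The same held for Treg against Tconv in 1B3 (1 of 35; 898, highest other 97), in 1B3.RAGKO (1 of 35; 804, 309) and in NOD (1 of 35; 922, 199), for 1B3.RAGKO_Tconv against 1B3_Tconv (1 of 35; 317, 247), and for the interaction with 1B3 (1 of 100; 68, 64). The Treg and Tconv divisions ignore that some samples share an animal. Only 8 in each strain, the real one included, part as many animals' Tconv and Treg, too few for a share under 0.05, and the highest others of these gave 97, 309 and 15. For 1B3.RAGKO_Treg against NOD_Treg 2 of 35 divisions gave as many (64, highest other 70), so chance is not excluded, and the other division moved the library labelled NOD_Treg replicate 1. For 1B3.RAGKO_Tconv against NOD_Tconv 3 of 35 did (317, highest other 775), so chance is not excluded there either. For the interaction with NOD 4 of 100 did (116, highest other 403), a share under 0.05, but these divisions have the limits of those for 1B3 and exclude no chance either. Both point to a structure besides the groups. The divisions with 775 and 247 set apart the Tconv with S100a9 at 14.48 to 16.99, against 6.84 to 8.13 in others. Other cells in these sorts may rival strain, although 309 and 258 Tconv rows passed with the covariate. For 1B3_Treg against NOD_Treg the 10 divisions, all of which gave 0 or more, are too few for a share under 0.05 (real value 0, highest other 2).

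In groups of 4 samples, 9 of 128 gene and group combinations had 1 sample far from the rest, where chance gives about 6.4. The gap over the range was 0.841 for Klrd1 and 0.927 for Arhgap29 in 1B3_Tconv replicate 1, 0.884 for Cacnb4 in 1B3.RAGKO_Treg replicate 4, and 0.925 for Tafa3, 0.861 for Gucy1b1 and 0.856 for C2cd4b in 1B3.RAGKO_Treg replicate 1. It was 0.977 for Nacc2 in NOD_Tconv replicate 4, 0.996 for Ptger3 in NOD_Tconv replicate 2 and 0.925 for Pla2g4f in NOD_Tconv replicate 3.

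Treg effects that differed between 1B3.RAGKO and 1B3, by the interaction test, were those of Nacc2 (4.775), Lrrc75b (4.278), Pdlim4 (3.662), Slpi (3.513), Cacnb4 (3.272), Ptger3 (-5.834), Penk (-4.65), Pla2g4f (-4.626), Tcrg (-4.214) and Capn3 (-3.993), and other passing probes of Nacc2, Slpi and Capn3 differed in sign. Ptger3 was well above background on 1 of the 8 1B3_Tconv arrays, so its value has no settled size. Between 1B3.RAGKO and NOD they were those of Nacc2 (4.88), Fam20a (3.833), Slpi (3.574), Ms4a1 (3.568), Tgfb3 (3.565), Ptger3 (-5.029), Penk (-4.959), C2cd4b (-4.937), Capn3 (-4.157) and Pla2g4f (-4.091). The green channel, which by the labels holds no sample, had 17.8% of probes well above background on the median array.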

How the results depend on the processing

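Alternatives chosen after the results had been seen were the lists and comparisons without the library labelled NOD_Treg replicate 1 where they do not use it, leaving out 4 libraries, and the monocyte, macrophage and neutrophil covariate. The others were fixed before. The counts below are given in the order of the comparisons of 1B3.RAGKO_Treg with 1B3_Treg (202) and with NOD_Treg (64), 1B3_Treg with NOD_Treg (0), Treg with Tconv in 1B3 (898), 1B3.RAGKO (804) and NOD (922), 1B3.RAGKO_Tconv with 1B3_Tconv (317) and NOD_Tconv (317), the interactions with 1B3 (68) and NOD (116), and the overlap (45). Only values that moved by more than 1.5 times are listed, so comparisons are named where some are passed over. The cause was not tested for any of them, apart from fewer samples or arrays taken as samples where the alternative is built so.

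With the processed signal the counts were 38, 22, 444 in 1B3, 401 in 1B3.RAGKO, 176 against 1B3_Tconv, 6 and 58 for the interactions and 4 shared. Under 75th percentile scaling they were 37, 6, 442, 403, 338, 180, 103, 22, 18 and 4, the 0 staying 0. The series table gave 562, 869, 7, then 489 and 540 for the Tconv, 194, 341 and 478. Requiring every sample above background gave 120 for the first. Fitting only the groups compared gave 377, 0, then 1874, 52, 334, 144, 70, 147, 28 and 0. All 42 arrays with the sample as a block gave 697, 412, 6, 1451, 1662, 1854, 881, 1122, 314, 612 and 278. With the slide as a block the first was 640, 1B3.RAGKO Treg against Tconv 1321, 1B3.RAGKO_Tconv against 1B3_Tconv 636 and the interaction with 1B3 129. Array weights gave 2647, 1619, 42, 6308, 321, 2202, 156 against NOD_Tconv, 180 for the interaction with 1B3 and 1141 shared. Without the 4 libraries the counts were 766, 873, 4, 2162, 1545, 615 against 1B3_Tconv, 315, 301 and 544. The covariate gave 94 for the first and 25 shared.

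Leaving out 1 library in turn gave 42 to 480, 2 to 435, 0 to 5, 387 to 1052, 409 to 981, 585 to 1052, 200 to 702, 185 to 1187, 23 to 167, 60 to 207, and 2 to 331 shared. With the animal as the replicate block the counts were 191, 47, 0, 1214, 1161, 927, 316, 292, 83, 96 and 32, none moved by more than 1.5 times. Of the 294 named gene values the block ended 27 calls and gained 1, given beside the results for the genes reported here, and changed no other. Of the 210 list tests, 87 passed without the block and 84 with it in camera run on the moderated t statistics, 10 calls being lost and 7 gained and none turned.

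The list tests past the threshold numbered 89, and 36 with an estimated correlation, 85 under 75th percentile scaling and 96 without the library labelled NOD_Treg replicate 1. Of 6844 values of named genes under an alternative, 5714 kept their direction and side of the threshold, 1071 lost the call, 51 gained it and 8 reversed. Ikzf2 between 1B3.RAGKO_Treg and NOD_Treg (-0.02) was -0.854 without the library labelled NOD_Treg replicate 1, 0.149 under 75th percentile scaling, 0.281 with the slide block, 0.177 with the covariate, 0.087 and 0.053 without 1B3.RAGKO_Treg replicates 1 and 3, and 0.398 and 0.384 without NOD_Treg replicates 2 and 3, and Ptgir in 1B3.RAGKO_Tconv against 1B3_Tconv was 0.12 where all samples had to be above background. Signal over background limits all of this: 55.7% to 74.9% of probes per array were well above it, and in 1B3_Treg against NOD_Treg simulated changes of 1 and 2 on the log2 scale were recovered in 23.9% and 71.6% of rows.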

Other observations

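All tests in this part were chosen after the results had been seen. Genes that separated NOD_Treg from NOD_Tconv were followed in the other strains, with a set chosen on the samples labelled NOD alone. Here and under 75th percentile scaling these samples included the library labelled NOD_Treg replicate 1. Its scanner files correlated most with 1B3.RAGKO_Treg (r = 0.329), so a choice made with it may not be independent of the 1B3.RAGKO samples. In that set of 261 higher genes the median Treg effect was 2.17 in 1B3 and 0.94 in 1B3.RAGKO, and the difference of effects had a median of -1.02 (limma's camera, adjusted p = 0.00104 with an estimated correlation, over 30 such tests). The same genes had a median difference of 1.2 between 1B3.RAGKO_Tconv and 1B3_Tconv (adjusted p = 0.000256) and of 0.19 between 1B3.RAGKO_Treg and 1B3_Treg (adjusted p = 0.434). The 73 lower genes had effects of -1.69 and -0.58, a difference of effects of 1.09 (adjusted p = 5.4e-06), and differences of -0.8 between the Tconv (adjusted p = 9.2e-06) and 0.09 between the Treg (adjusted p = 0.0374).

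Chosen without the library labelled NOD_Treg replicate 1, 362 higher genes had a difference of effects of -1.3 (adjusted p = 0.000114), 0.75 between the Tconv (adjusted p = 0.00104) and -0.35 between the Treg (adjusted p = 0.0359), so the sign of the Treg difference turned, and 131 lower genes had 1.2 (adjusted p = 2.77e-05), -0.52 (adjusted p = 0.00255) and 0.66 (adjusted p = 0.000508). Under 75th percentile scaling 15 higher genes had -2.76 (adjusted p = 0.000219), 3.32 between the Tconv (adjusted p = 0.000183) and -0.04 between the Treg (adjusted p = 0.999), and 13 lower genes had 2.15 (adjusted p = 2.25e-05), -1.75 (adjusted p = 1.73e-05) and 0.19 (adjusted p = 0.227).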
